A study of Homo sapiens with 14 samples.

How the data were processed

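The series held 14 human K562-Cas9 samples in 7 groups of 2, and the processed data came as 8 tables of the authors' own gene-level results: for each of 4 sorted gates against the unsorted cells of its day, 1 MAGeCK gene summary and 1 casTLE table. These tables held no sgRNA counts and no values of single libraries, so 0 columns of per-sample values were used and the depth per sample is unknown. Neither a new fit, a fit with replicate as a block, nor a simulation of the shared unsorted libraries was run. The submitters' processing notes named MAGeCK without a version, and casTLE was known from the tables themselves. The sgRNA library, the alignment, the scaling of counts, the direction of the ratio and whether both replicates entered 1 run were not stated.

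Per the file headers, the deposited MAGeCK tables gave a p-value and an FDR per gene and direction, the log2 fold change, a robust rank aggregation score, and other columns with ranks and numbers of sgRNAs. The deposited casTLE tables gave an effect score, in an enrichment unit whose log base and scaling were not stated, for each of 2 numbered inputs and combined, with a minimum and a maximum effect estimate, a likelihood-ratio score and a permutation p-value whose smallest value was 1e-06. The inputs were taken as the replicates, which the headers did not state. The smallest deposited MAGeCK p-value was 2.4e-07. The sign was settled from COX4I1, the gene of the stained COX4: positive stands for enrichment in the gate.

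Each MAGeCK table held 20464 genes, with a median of 10 sgRNAs per gene and 913 to 920 genes under 8. Symbols were matched to the casTLE tables without regard to case. Repeated symbols stayed unmatched, as did 29 symbols per casTLE table that had turned into dates, which left 98 to 99 genes without a casTLE value. Current names were found for 19438 genes in the RefSeq gene table, which was also used for the order of genes on chromosomes 9 and 22.

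Genes were called at the authors' deposited MAGeCK FDR under 0.05 in either direction. Calls of 30 gene lists, fixed before the data were examined, were compared with all other genes by two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the 240 tests of lists, gates and directions. The lists covered the mitochondrial ribosome, its assembly, translation factors, aminoacyl-tRNA synthetases, mitochondrial transcription, RNA processing and mtDNA maintenance. Respiratory complexes I to V and their assembly, coenzyme Q, the TCA cycle, lipoylation, iron-sulfur clusters and heme, import, chaperones and phospholipids were lists too. Others held one-carbon and NAD metabolism, nuclear regulators, mTOR, stress responses, erythroid genes and general growth machinery. For each list the number of members past 0.05 after adjustment over the list alone was counted as well. Overlaps of calls were tested by Fisher's exact test and adjusted over all pairs. Gates of 1 day were compared gene by gene on the casTLE effects, with a standard error from each deposited interval (its width over 2 times 1.96), a two-sided normal approximation and Benjamini-Hochberg adjustment. This treats the deposited bounds as 95% intervals and leaves out that both gates shared unsorted libraries. The z values of olfactory receptor genes had an SD of 0.856 at day 10 and 0.816 at day 14. Olfactory receptor genes (388) served as the background of calls and correlations, with exact Clopper-Pearson intervals.

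Genes were named by a rule set before the data were examined: the 12 best-ranked calls per comparison and direction, the 4 best-ranked called members of each passing list, and in every comparison COX4I1, PREPL, NME6, LRPPRC, TFAM, POLRMT and PNPT1. Genes named as shared between gates, or called in both directions, and COX5A in the lower-right gate were chosen after their values were seen. A few genes that the rule named are not reported here, while the counts include them.

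Alternatives tried were casTLE calls (Benjamini-Hochberg of the deposited p under 0.05), calls of both tools, FDR thresholds of 0.01, 0.1 and 0.25, and FDR recomputed from the deposited p. Minimums of 8 sgRNAs, of 4 good sgRNAs and of 0.5 in log2 fold change were also tried, as were each casTLE input alone, listed genes as background, the median of each list against 10000 random lists of genes (a gene permutation test, drawn with replacement), and casTLE effects for correlations. The tests were checked on simulated noise that replaced the deposited values, with 200 changed genes planted. For the list test, 195 of 200 changed and 9 unchanged genes were called. The 1 list with planted genes passed, and 0 lists without them did. The difference test called 115 of 200 changed and 9 unchanged genes at day 10 and 106 of 200 and 4 at day 14. The planted differences were larger than most of those reported here, and standard errors were held within fixed bounds. How many smaller differences the test would find is therefore unknown. The simulated gates had independent noise, so this check leaves out the effect of shared unsorted libraries. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.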

Results

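Pooled CRISPR knockout screens were read out by flow sorting of human K562 cells, a chronic myeloid leukaemia line, that stably expressed Cas9 and carried a genome-wide sgRNA library. The cells were fixed in methanol and stained for COX1, a core subunit of respiratory complex IV encoded by mitochondrial DNA (mtDNA), and for COX4, a subunit of the same complex encoded in the nucleus. The study asked which genes regulate the balance between both genomes. Its 14 samples formed 7 groups of 2: cells at day 0, unsorted cells at day 10, a day 10 gate high for both stains, a day 10 gate low for both stains, unsorted cells at day 14, and 2 off-diagonal gates at day 14, lower-right and upper-left. The file names of both day 14 comparisons also carried a both-low tag, which the sample labels did not. The labels did not state which stain lay on which axis of the off-diagonal gates. They named K562 as the cell line of 8 samples, and for the 6 day 14 samples they gave K562-like names whose number rose by 1 per sample. Each of the 4 sorted gates was set against the unsorted cells of its day, and the day 0 samples were not analysed here. The values came from the authors' deposited gene-level tables, which held no read counts, so the depth per library is unknown. A positive value stands for sgRNAs enriched in the gate over unsorted cells. The tables did not name this direction, and it was taken from COX4I1, which encodes COX4: its sgRNAs were depleted in the both-high gate and enriched in the both-low gate. A gene is called here at a deposited MAGeCK FDR under 0.05, and the exact tests of lists and overlaps are two-sided Fisher's exact tests. The log2 fold changes have no deposited error, so the casTLE effect of the same gene is given with its deposited minimum and maximum estimates, in casTLE's own unit.

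The both-low gate of day 10 held an excess of sgRNAs against genes of mitochondrial gene expression and of complex IV. In the authors' deposited MAGeCK table, 267 of 20464 genes were enriched and 61 were depleted. TRMU (ENSG00000100416), which thiolates mitochondrial tRNAs, ranked best among the enriched genes, with a deposited log2 fold change of 1.25 and a deposited casTLE effect of 2.0 (1.3 to 2.6). COX4I1 (ENSG00000131143), the gene of the stained nuclear subunit, had a deposited log2 fold change of 0.90 and a casTLE effect of 2.0 (0.9 to 3.3). MMADHC (ENSG00000168288), a cobalamin trafficking gene, ranked best among the depleted genes at a deposited log2 fold change of -1.23 and a casTLE effect of -1.3 (-1.8 to -1.1).

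Mitochondrial translation made up the broadest enriched block of this gate. Of 82 measured genes of the mitochondrial ribosome, 34 were enriched in the authors' deposited MAGeCK table, 69 when adjusted over the list alone (exact test, adjusted p = 1.8e-40). MRPS31, MRPS27 and MRPS34 had deposited log2 fold changes of 1.27, 0.88 and 1.04. Ribosome assembly factors were enriched for 18 of 28 genes, 22 when adjusted over the list alone (exact test, adjusted p = 6.3e-26), among them the rRNA endonuclease YBEY at 1.24, METTL17 at 1.40 and the GTPase GTPBP10 at 1.05 in log2 fold change of the deposited table. Translation factors followed with 12 of 18 genes, 13 when adjusted over the list alone (exact test, adjusted p = 1.6e-17), including the elongation factor TUFM at a deposited log2 fold change of 1.12 and TACO1, the translational activator of COX1, at 0.98. Mitochondrial aminoacyl-tRNA synthetases had 9 of 20 genes enriched, 18 when adjusted over the list alone (exact test, adjusted p = 3.1e-11), with deposited log2 fold changes of 0.83 for SARS2 and 0.71 for NARS2. RNA processing and stability had 14 of 38, 19 when adjusted over the list alone (exact test, adjusted p = 7.4e-16). Its leading members modify the wobble base of mitochondrial tRNAs: besides TRMU, GTPBP3 and MTO1 had deposited log2 fold changes of 1.17 and 0.98. PNPT1, a mitochondrial RNA exonuclease, was enriched at 0.74 in the deposited table. Mitochondrial transcription had 2 of 6 genes enriched, 5 when adjusted over the list alone (exact test, adjusted p = 0.0111): the mitochondrial RNA polymerase POLRMT at a deposited log2 fold change of 0.60 and its partner TFB2M at 0.54.

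Respiratory chain genes were enriched in the same gate. Complex IV assembly factors had 18 of 34 genes called in the authors' deposited MAGeCK table, 25 when adjusted over the list alone (exact test, adjusted p = 7.4e-24), with deposited log2 fold changes of 0.89 for the heme A synthase COX15, 0.82 for CMC1 and 0.67 for COX16. Its subunits had 7 of 18, 10 when adjusted over the list alone (exact test, adjusted p = 2.4e-08), including COX7C at 1.11, COX5B at 0.76 and COX5A at 0.64 in deposited log2 fold change. Complex I subunits had 11 of 37, 26 when adjusted over the list alone (exact test, adjusted p = 2.3e-11), and complex I assembly factors 8 of 19, 12 when adjusted over the list alone (exact test, adjusted p = 8.7e-10). NDUFA1 and the iron-sulfur carrier NUBPL had deposited log2 fold changes of 1.01 and 1.04. Complex V was enriched for 3 of 21 genes, 4 when adjusted over the list alone (exact test, adjusted p = 0.0111), namely ATPAF2, ATP5A1 and ATP5I at deposited log2 fold changes of 0.63, 0.55 and 0.65. The median of complex V, 0.032, did not pass against random lists (gene permutation test, adjusted p = 0.378). Smaller counts passed for complex II and the TCA cycle (4 of 31, 10 when adjusted over the list alone, exact test, adjusted p = 0.00338), with PDHA1 at 0.82 and citrate synthase CS at 0.62 in the deposited table. Lipoylation and mitochondrial fatty acid synthesis had 4 of 10, 6 when adjusted over the list alone (exact test, adjusted p = 4.8e-05), with the lipoyl synthase LIAS at a deposited log2 fold change of 0.74. Iron-sulfur cluster and heme synthesis had 6 of 29, 9 when adjusted over the list alone (exact test, adjusted p = 1.6e-05), with BOLA3 at a deposited 0.75 and ISCA2 at 0.72. Protein import had 4 of 39, 7 when adjusted over the list alone (exact test, adjusted p = 0.00766), with TOMM70A at a deposited 0.71. Chaperones and proteases had 3 of 18, 5 when adjusted over the list alone (exact test, adjusted p = 0.00745), with CLPP at 0.63.

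Depleted genes of the both-low gate were fewer, and 2 lists passed among them. mtDNA replication and maintenance had 3 of 23 genes depleted in the authors' deposited MAGeCK table, 3 when adjusted over the list alone (exact test, adjusted p = 0.000285). The median log2 fold change of this list, -0.036, did not pass against random lists (gene permutation test, adjusted p = 0.538). These were the mtDNA nuclease MGME1 at a deposited log2 fold change of -0.69 and the pyrimidine nucleotide carriers SLC25A33 at -0.66 and SLC25A36 at -0.42. NME6, a nucleoside diphosphate kinase family member of mitochondria, had a deposited log2 fold change of -1.02 with a casTLE effect of -1.5 (-2.2 to -1.1), and TYMS, the thymidylate synthase, -1.26 with -2.2 (-2.8 to -1.8). Of the mTOR pathway, 2 of 43 genes were depleted, 3 when adjusted over the list alone (exact test, adjusted p = 0.0302): RRAGA and LAMTOR2, parts of the lysosomal amino acid sensing machinery, at deposited log2 fold changes of -0.47 and -0.76. GPI, the glycolytic isomerase, stood at a deposited -1.05.

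Of the calls in the both-low gate that could be matched, casTLE effects carried the direction of the call in both of its inputs for 97.0% of enriched and 98.4% of depleted genes. The authors' deposited casTLE table called 209 genes enriched and 115 depleted after Benjamini-Hochberg adjustment, of which 164 and 35 were also MAGeCK calls. By casTLE calls, complex II and the TCA cycle, chaperones and proteases, and the mTOR pathway did not pass. With only the genes of the 30 lists as background, 7 of the 18 passing list tests of this gate passed. These were the mitochondrial ribosome, its assembly, translation factors, aminoacyl-tRNA synthetases, RNA processing, complex IV assembly and, depleted, mtDNA maintenance.

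**Figure D1:**
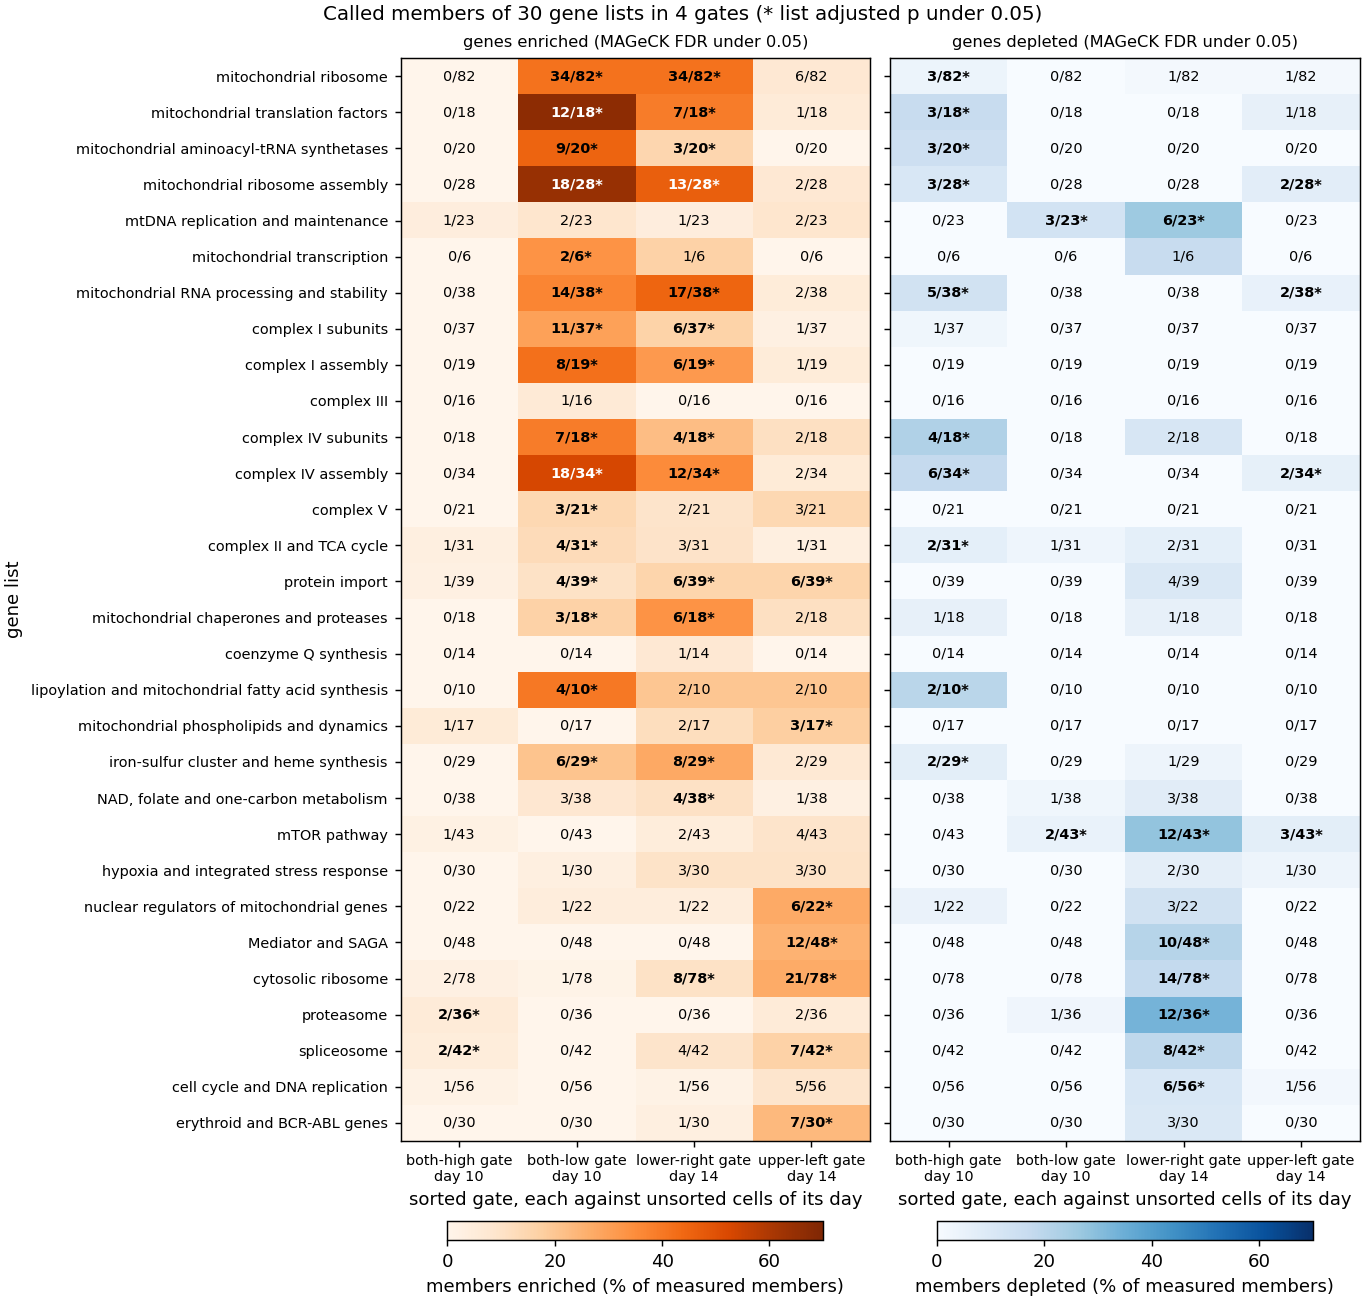
Each cell gives the called over the measured members of a gene list (rows) in one gate (columns), coloured by the percent of measured members enriched (left, orange) or depleted (right, blue) at a deposited MAGeCK FDR under 0.05; bold counts with an asterisk mark lists with an adjusted p under 0.05. The mitochondrial ribosome had 34 of 82 genes enriched in both the both-low and the lower-right gate, and the proteasome had 12 of 36 depleted in the lower-right gate.

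The both-high gate of day 10 showed the opposite directions for many of these genes, with fewer calls. In the authors' deposited MAGeCK table, 63 genes were enriched and 57 depleted. TRMU was again the best-ranked gene, now depleted, with a deposited log2 fold change of -1.24 and a casTLE effect of -2.2 (-2.9 to -1.7). COX4I1 stood at a deposited log2 fold change of -1.18 and a casTLE effect of -1.7 (-2.5 to -1.3). MMADHC led the enriched genes at a deposited log2 fold change of 0.80 and a casTLE effect of 0.9 (0.6 to 1.5), followed by NME6 at 0.80 with 0.8 (0.5 to 1.5) and MGME1 at 0.62 with 0.8 (0.4 to 1.2).

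Complex IV and mitochondrial gene expression made up most of the depleted lists. Complex IV assembly had 6 of 34 genes depleted in the authors' deposited MAGeCK table, 14 when adjusted over the list alone (exact test, adjusted p = 7.2e-09), with deposited log2 fold changes of -0.79 for COA7, -0.87 for COA3, -0.86 for COX18 and -0.75 for TACO1. Complex IV subunits had 4 of 18, 6 when adjusted over the list alone (exact test, adjusted p = 1.7e-06): besides COX4I1, COX8A at -1.57 on 5 sgRNAs, COX5B at -0.65 and COX5A at -0.59. RNA processing and stability had 5 of 38, 18 when adjusted over the list alone (exact test, adjusted p = 7.5e-07), with GTPBP3 at a deposited log2 fold change of -0.93, MTO1 at -0.69 and the pseudouridine synthase PUS1 at -0.25. Translation factors had 3 of 18, 9 when adjusted over the list alone (exact test, adjusted p = 0.000118). Aminoacyl-tRNA synthetases had 3 of 20, 5 when adjusted over the list alone (exact test, adjusted p = 0.000155), and ribosome assembly 3 of 28, 13 when adjusted over the list alone (exact test, adjusted p = 0.000414). The mitochondrial ribosome had 3 of 82, 29 when adjusted over the list alone (exact test, adjusted p = 0.00745), with MRPS34 at a deposited -1.18 and MRPL44 at -0.70. MRPS17 stood at a deposited -0.49, but its symbol was repeated in the casTLE table and has no casTLE value here. Lipoylation had 2 of 10, 4 when adjusted over the list alone (exact test, adjusted p = 0.00189), namely MCAT at a deposited -0.90 and LIAS at -0.76. Complex II and the TCA cycle had 2 of 31, 5 when adjusted over the list alone (exact test, adjusted p = 0.0144), namely PDHB at a deposited -0.94 and CS at -0.67. Iron-sulfur cluster and heme synthesis had 2 of 29, 11 when adjusted over the list alone (exact test, adjusted p = 0.0129), namely the cysteine desulfurase NFS1 at a deposited -0.68 and BOLA3 at -0.86.

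Among the enriched genes of the both-high gate stood enzymes of glycolysis, with deposited log2 fold changes of 0.68 for the pyruvate kinase PKM and 0.82 for the triosephosphate isomerase TPI1. The proteasome had 2 of 36 genes enriched in the authors' deposited MAGeCK table, 8 when adjusted over the list alone (exact test, adjusted p = 0.0231), namely PSMB4 at 0.78 and PSMD2 at 0.68. The spliceosome also had 2 of 42, 8 when adjusted over the list alone (exact test, adjusted p = 0.0302), namely PHF5A at a deposited 0.68 and SNRPD3 at 0.67, the latter with casTLE effects of opposite sign in the 2 inputs (2.2 and -1.2). The authors' deposited casTLE table called 23 genes enriched and 62 depleted, of which 12 and 29 were also MAGeCK calls. By casTLE calls the iron-sulfur cluster and heme list did not pass. With only the genes of the 30 lists as background, 2 of the 12 passing list tests of this gate passed, those of complex IV subunits and assembly.

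Calls of the 2 day 10 gates opposed each other. Of the 57 genes depleted in the both-high gate, 38 were enriched in the both-low gate, against 0.744 expected of independent lists (exact test, adjusted p = 6.6e-58). Of the 63 genes enriched in the both-high gate, 11 were depleted in the both-low gate, against 0.188 expected (exact test, adjusted p = 1.2e-16). These were CHD8, HK2, IDH3B, LAMTOR2, MGME1, MMADHC, MYLIP, NME6, SETD1B, SLC25A5 and SLC4A7. Tested on the deposited casTLE effects and their intervals, 325 of 20364 genes differed between the gates, 233 with the higher effect in the both-low gate and 92 with the higher effect in the both-high gate (normal approximation, Benjamini-Hochberg). Among these genes the difference was 4.2 in TRMU and 3.7 in COX4I1 toward the both-low gate. Across all genes the log2 fold changes of both gates had a Pearson r of -0.03, and among 388 olfactory receptor genes, taken as unused in these cells, r was 0.28. Genes are not independent replicates. Both gates shared their unsorted libraries. Between gates of different days, which shared none, r among olfactory receptor genes ran from -0.07 to 0.29. On casTLE effects, r among olfactory receptor genes was 0.23 between the day 10 gates and -0.09 to 0.14 between gates of different days.

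**Figure D2:**
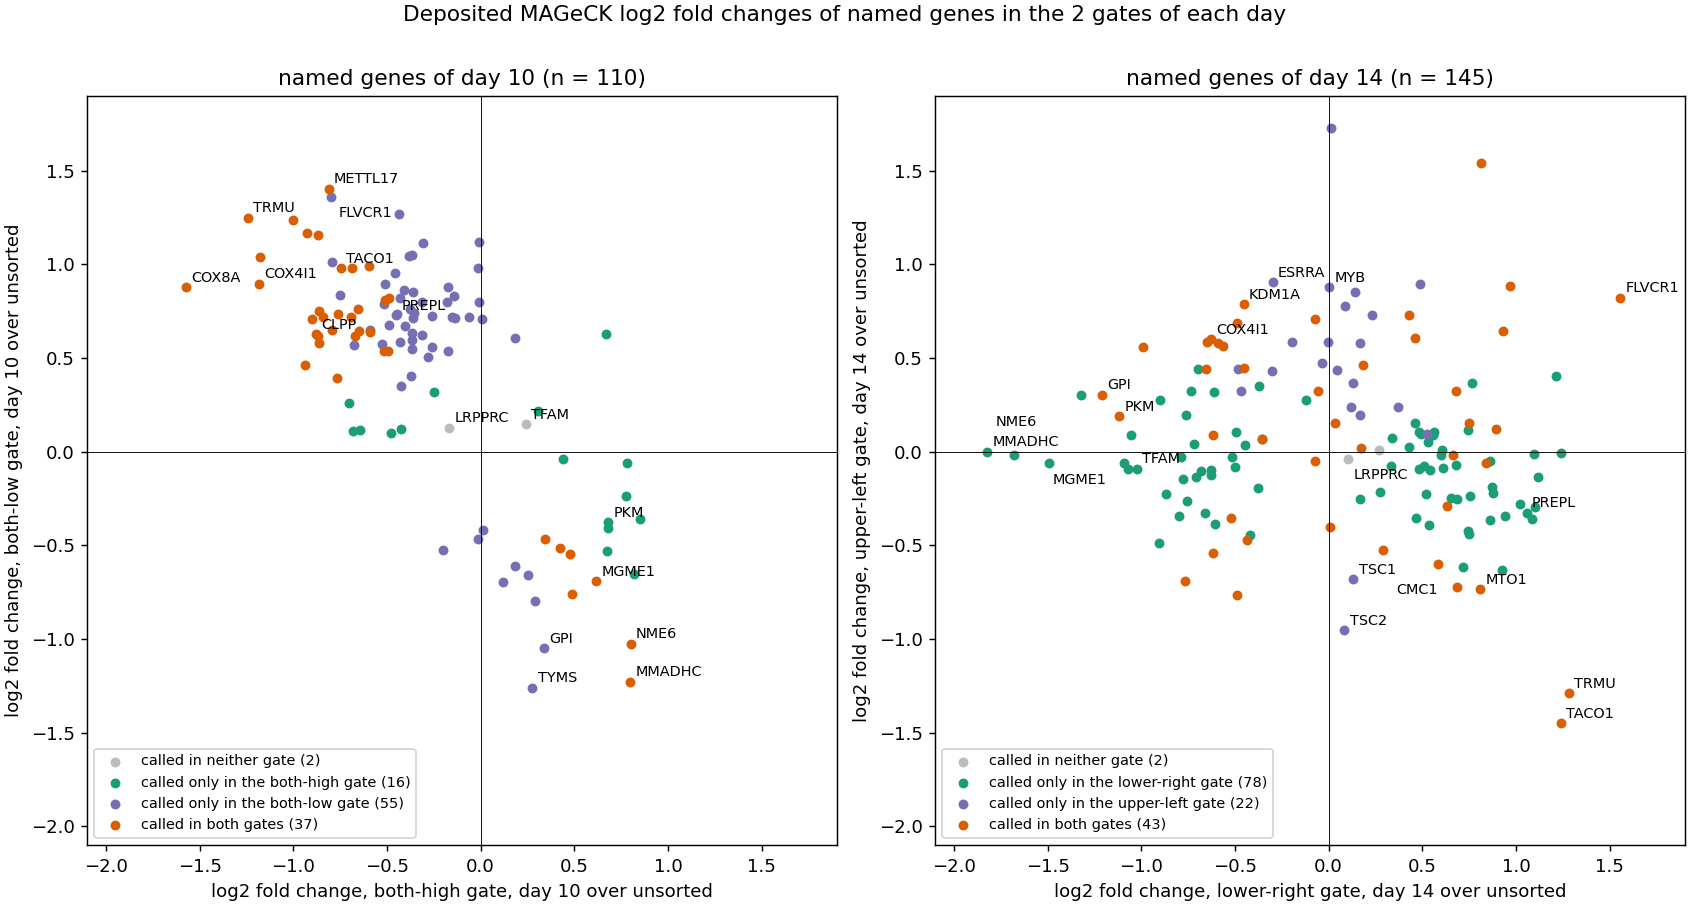
Each point is a named gene, with the deposited MAGeCK log2 fold change over unsorted cells in one gate on the x axis and in the other gate of the same day on the y axis, for 110 genes at day 10 (left) and 145 at day 14 (right); colours give the gates in which the gene was called. At day 10, TRMU lay at -1.24 and 1.25 and MMADHC at 0.80 and -1.23, and at day 14, TRMU lay at 1.28 and -1.29.

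The lower-right gate of day 14 combined an excess of sgRNAs against mitochondrial gene expression with a loss of sgRNAs against the mTOR pathway, the proteasome and COX4I1. In the authors' deposited MAGeCK table, 454 genes were enriched and 521 depleted. The best-ranked enriched gene was TRMU, with a deposited log2 fold change of 1.28 and a casTLE effect of 2.0 (1.5 to 2.7). TACO1 (ENSG00000136463) had 1.24 with 2.2 (1.5 to 3.1) and PREPL (ENSG00000138078), a prolyl endopeptidase-like protein, 1.06 with 1.8 (1.3 to 2.5). MMADHC led the depleted genes at a deposited log2 fold change of -1.82 with -2.4 (-3.1 to -2.0), followed by NME6 at -1.68 with -2.0 (-2.7 to -1.6) and MGME1 at -1.49 with -1.9 (-3.5 to -1.5). COX4I1 was depleted at a deposited -0.63, with a casTLE effect of -1.8 (-2.8 to -1.3).

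The mitochondrial ribosome had 34 of 82 genes enriched in the authors' deposited MAGeCK table, 59 when adjusted over the list alone (exact test, adjusted p = 1.0e-32), with MRPS26 at 1.10, MRPL43 at 1.24 and MRPS34 at 1.09 in deposited log2 fold change. RNA processing and stability had 17 of 38, 26 when adjusted over the list alone (exact test, adjusted p = 4.3e-17), including PUS1 at a deposited 0.93 and the RNases PDE12 at 1.08 and ANGEL2 at 0.76. Ribosome assembly had 13 of 28, 22 when adjusted over the list alone (exact test, adjusted p = 2.0e-13), with RPUSD4 at 0.97, TFB1M at 0.87 and YBEY at 0.86 in the deposited table. Complex IV assembly had 12 of 34, 25 when adjusted over the list alone (exact test, adjusted p = 8.7e-11), with COA3 at 0.94, SCO2 at 0.77 and CMC1 at 0.69 in deposited log2 fold change. Translation factors had 7 of 18, 16 when adjusted over the list alone (exact test, adjusted p = 7.5e-07), and the aminoacyl-tRNA synthetases 3 of 20, 13 when adjusted over the list alone (exact test, adjusted p = 0.0367). Complex IV subunits were split. There, 4 of 18 were enriched, 7 when adjusted over the list alone (exact test, adjusted p = 0.00298), with COX7C at a deposited 1.12, COX5B at 1.02 and COX8A at 0.72, while COX4I1 and COX5A, its partner in early assembly, were depleted at -0.63 and -0.41. TFB2M was enriched at a deposited 1.21, with a casTLE effect of 1.8 (1.3 to 2.5), and POLRMT stood at 0.27 (FDR 0.497), with 2.4 (1.3 to 4.2).

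Further mitochondrial lists passed with smaller counts in the lower-right gate. Iron-sulfur cluster and heme synthesis had 8 of 29 enriched, 17 when adjusted over the list alone (exact test, adjusted p = 1.7e-06), with the scaffold ISCU at a deposited log2 fold change of 0.93. Chaperones and proteases had 6 of 18, 8 when adjusted over the list alone (exact test, adjusted p = 1.6e-05), with TRAP1 at a deposited 0.74 and CLPP at 0.69. HSPE1, at a deposited 0.82, had a casTLE effect of the other sign (-1.5), and the list's median log2 fold change, -0.00485, did not pass against random lists (gene permutation test, adjusted p = 0.963). Complex I assembly had 6 of 19, 12 when adjusted over the list alone (exact test, adjusted p = 2.2e-05), and complex I subunits 6 of 37, 15 when adjusted over the list alone (exact test, adjusted p = 0.000921), with NDUFAF3 at a deposited 0.84 and NDUFB4 at 0.61. Protein import had 6 of 39, 12 when adjusted over the list alone (exact test, adjusted p = 0.00121), with the outer membrane translocase genes TOMM22 at a deposited 0.89 and TOMM40 at 0.86. NAD, folate and one-carbon metabolism had 4 of 38, 6 when adjusted over the list alone (exact test, adjusted p = 0.0376), among them NAMPT and SLC25A26, the mitochondrial S-adenosylmethionine carrier, at deposited log2 fold changes of 0.53 and 0.48. The median of that list, 0.043, did not pass against random lists (gene permutation test, adjusted p = 0.13).

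Depleted lists of the lower-right gate included mtDNA replication and maintenance with 6 of 23 genes in the authors' deposited MAGeCK table, 9 when adjusted over the list alone (exact test, adjusted p = 0.00013). The median log2 fold change of this list, -0.052, did not pass against random lists (gene permutation test, adjusted p = 0.329). After MGME1 came TFAM, which packages mtDNA, at a deposited log2 fold change of -1.02 with a casTLE effect of -1.4 (-2.1 to -1.0), and the mtDNA polymerase subunits POLG at -0.63 and POLG2 at -0.68. The mTOR pathway had 12 of 43, 18 when adjusted over the list alone (exact test, adjusted p = 7.3e-09), with LAMTOR2 at a deposited -0.74, RRAGA at -0.72, PDPK1 at -0.65 and MLST8 at -0.59. The proteasome had 12 of 36, 26 when adjusted over the list alone (exact test, adjusted p = 8.7e-10), with PSMA3 at a deposited -0.87 and PSMD12 at -0.63. Transcriptional coactivators of the Mediator and SAGA list had 10 of 48, 22 when adjusted over the list alone (exact test, adjusted p = 2.9e-06), with MED12 at a deposited -0.70. The spliceosome had 8 of 42, 19 when adjusted over the list alone (exact test, adjusted p = 7.4e-05), with XAB2 at a deposited -0.76. Cell cycle and DNA replication had 6 of 56, 16 when adjusted over the list alone (exact test, adjusted p = 0.0129), with CCND3 at -0.77 and CDK6 at -0.66. Cytosolic ribosome genes were called in both directions: 14 of 78 depleted, 40 when adjusted over the list alone (exact test, adjusted p = 1.2e-07), with RPS4X at a deposited -0.99 and RPL12 at -0.91, and 8 of 78 enriched, 20 when adjusted over the list alone (exact test, adjusted p = 0.00189). The list's median log2 fold change was -0.14, and the 4 best-ranked enriched members, RPL7, RPL35A, RPS9 and RPS23, had deposited values of -0.37, -0.07, -0.12 and 0.03, so that only RPS23 had a log2 fold change with the sign of its call. Outside the lists, the glycolytic genes GPI, PKM, HK2 and PFKP were depleted at deposited log2 fold changes of -1.21, -1.12, -1.07 and -0.76, and the phosphoglycolate phosphatase PGP at -1.05.

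Of the genes called in the lower-right gate, the authors' deposited casTLE table called 49 of 454 enriched and 63 of 521 depleted genes with the same sign. Of the calls with casTLE values, both casTLE inputs had the direction of the call for 76.6% of the enriched and 83.5% of the depleted genes. The 5 genes DRAP1, MCMBP, SNRPB, SRP54 and ZNHIT2 were called in both directions. By casTLE calls, the lists of aminoacyl-tRNA synthetases, complex I subunits and assembly, protein import, iron-sulfur clusters and heme, and one-carbon metabolism did not pass. Nor did Mediator and SAGA, the spliceosome, the cell cycle, or the cytosolic ribosome in either direction. With only the genes of the 30 lists as background, 5 of the 21 passing list tests of this gate passed. These were the mitochondrial ribosome, its assembly and RNA processing among enriched lists, and the mTOR pathway and the proteasome among depleted lists.

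The upper-left gate of day 14 had few depleted genes, among them mitochondrial genes and inhibitors of the mTOR pathway, and many enriched genes with small changes. In the authors' deposited MAGeCK table, 532 genes were enriched and 20 depleted. TACO1 ranked best among the depleted genes with a deposited log2 fold change of -1.45 and a casTLE effect of -2.6 (-3.4 to -2.1), then TRMU with -1.29 and -2.4 (-3.2 to -2.0) and TSC2, a brake on mTORC1, with -0.95 and -1.4 (-2.2 to -1.1). ESRRA (ENSG00000173153), the nuclear receptor that drives mitochondrial genes, ranked best among the enriched genes with 0.91 and 1.3 (0.9 to 1.9), followed by the histone demethylase KDM1A with 0.79 and 1.1 (0.8 to 1.6). COX4I1 was enriched at a deposited 0.60, with a casTLE effect of 0.9 (0.5 to 2.7).

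Among depleted lists of the upper-left gate, the mTOR pathway had 3 of 43 genes in the authors' deposited MAGeCK table, 7 when adjusted over the list alone (exact test, adjusted p = 7.4e-05): TSC2, its partner TSC1 at -0.68, and NPRL3, a subunit of another mTORC1 inhibitor, at -0.53. The list's median log2 fold change, 0.023, did not pass against random lists (gene permutation test, adjusted p = 0.13). Other members of the mTOR list went the other way: MLST8 and PDPK1 were called enriched in the upper-left and depleted in the lower-right gate. NPRL3 was called enriched in the lower-right gate. Ribosome assembly had 2 of 28, 7 when adjusted over the list alone (exact test, adjusted p = 0.00189), namely METTL17 at a deposited -0.60 and MPV17L2 at -0.02, whose casTLE effect was 2.3. RNA processing and stability had 2 of 38, 7 when adjusted over the list alone (exact test, adjusted p = 0.00319), TRMU and MTO1 at a deposited -1.29 and -0.73. Complex IV assembly had 2 of 34, 3 when adjusted over the list alone (exact test, adjusted p = 0.00266), TACO1 and CMC1 at a deposited -1.45 and -0.72. The median of that list, -0.063, did not pass against random lists (gene permutation test, adjusted p = 0.17).

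Enriched lists of the upper-left gate began with nuclear regulators of mitochondrial genes, 6 of 22 in the authors' deposited MAGeCK table, 7 when adjusted over the list alone (exact test, adjusted p = 0.000118). After ESRRA came its coactivator PPARGC1B at a deposited log2 fold change of 0.58, SP1 at 0.45 and NRF1 at 0.09. Mediator and SAGA had 12 of 48, 29 when adjusted over the list alone (exact test, adjusted p = 3.3e-08), with MED10 at a deposited 0.59 and TADA2B at 0.56. The erythroid and BCR-ABL list, genes on which this leukaemia line depends, had 7 of 30, 13 when adjusted over the list alone (exact test, adjusted p = 7.4e-05), with the transcription factors MYB at a deposited 0.88, KLF1 at 0.59 and GATA1 at 0.33 and the kinase ABL1, called by MAGeCK, at -0.05. Cytosolic ribosome genes had 21 of 78, 52 when adjusted over the list alone (exact test, adjusted p = 1.5e-14), with RPS13 at a deposited 0.73. The spliceosome had 7 of 42, 22 when adjusted over the list alone (exact test, adjusted p = 0.000597), with SNRNP200 at a deposited 0.85 and SNRPD1 at -0.40. Protein import had 6 of 39, 10 when adjusted over the list alone (exact test, adjusted p = 0.00258), with HSPA9 at a deposited 0.61 and TIMM23 at 0.10. Phospholipids and dynamics had 3 of 17, 5 when adjusted over the list alone (exact test, adjusted p = 0.0362), namely DNM1L, PTPMT1 and CRLS1 at deposited values of 0.07, 0.33 and 0.20, each with a casTLE effect below 0 in input 2. Of these 7 enriched lists, 5 did not pass by their medians against random lists. By this gene permutation test they were nuclear regulators (median 0.052, adjusted p = 0.0615), the erythroid and BCR-ABL list (0.040, adjusted p = 0.0707) and the spliceosome (0.023, adjusted p = 0.132). Protein import (0.011, adjusted p = 0.31) and phospholipids and dynamics (-0.00454, adjusted p = 0.751) did not pass the gene permutation test either.

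Enriched calls of the upper-left gate rested on weaker ground than those of the other gates. Their median deposited log2 fold change was 0.30, 63 of the 532 had a log2 fold change below 0, and casTLE called 21 of them. Both casTLE inputs had the direction of the call for 353 (66.9%) of the 528 with casTLE values. Across all genes the effects of the 2 inputs had Spearman correlations of -0.079, 0.178, 0.013 and 0.043 in the both-high, both-low, lower-right and upper-left gates. Among genes called in either direction these were 0.634, 0.582, 0.536 and -0.008. Genes called in opposite directions raise such a correlation by themselves. The upper-left gate had 532 enriched but only 20 depleted calls, against 454 and 521 in the lower-right gate. The correlations among called genes therefore cannot rank the enriched calls of the gates. By casTLE calls none of the 7 enriched lists of the upper-left gate passed, nor did the depleted ribosome assembly list. With only the genes of the 30 lists as background, 1 of its 11 passing list tests passed, that of the enriched cytosolic ribosome.

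The 2 day 14 gates shared and opposed calls. Of the 20 genes depleted in the upper-left gate, 9 were enriched in the lower-right gate, against 0.443 expected of independent lists (exact test, adjusted p = 3.8e-10). These were CMC1, METTL17, MPV17L2, MRPS17, MTO1, NPRL3, TACO1, TRMU and the MRPS24 readthrough locus URGCP-MRPS24. Of the genes depleted in the lower-right gate, 41 were enriched in the upper-left gate, against 13.5 expected (exact test, adjusted p = 7.2e-10), among them COX4I1, COX5A, KDM1A and SP1. By casTLE calls this overlap held 0 genes against 0.0856 expected, too few to decide. Calls in the same direction also overlapped, with 110 genes enriched in both gates against 11.8 expected of independent lists and 7 depleted in both against 0.509. casTLE calls left 3 genes enriched in both, against 0.0645 expected. These lists are not independent, because both gates were set against the same unsorted libraries, and the overlap that this alone gives was not estimated. FLVCR1, a choline and heme transporter, was enriched at a deposited log2 fold change of 1.55 in the lower-right and 0.82 in the upper-left gate. The log2 fold changes of both gates correlated across genes at r = 0.27, with a covariance of 0.00876, and across olfactory receptor genes at r = 0.24, with a covariance of 0.00464. The both-high and upper-left gates, which shared no unsorted libraries, had an olfactory receptor r of 0.29, with a covariance of 0.00529. On casTLE effects the olfactory receptor r was 0.39 between the day 14 gates and 0.04 between the both-high and upper-left gates. By the test of the casTLE effects, 200 of 20365 genes differed between the gates, 82 with the higher effect in the lower-right and 118 with the higher effect in the upper-left gate. Among these genes TRMU differed by 4.4, TACO1 by 4.8 and PREPL by 3.6 toward the lower-right gate, and KDM1A by 2.2 toward the upper-left gate.

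**Figure D3:**
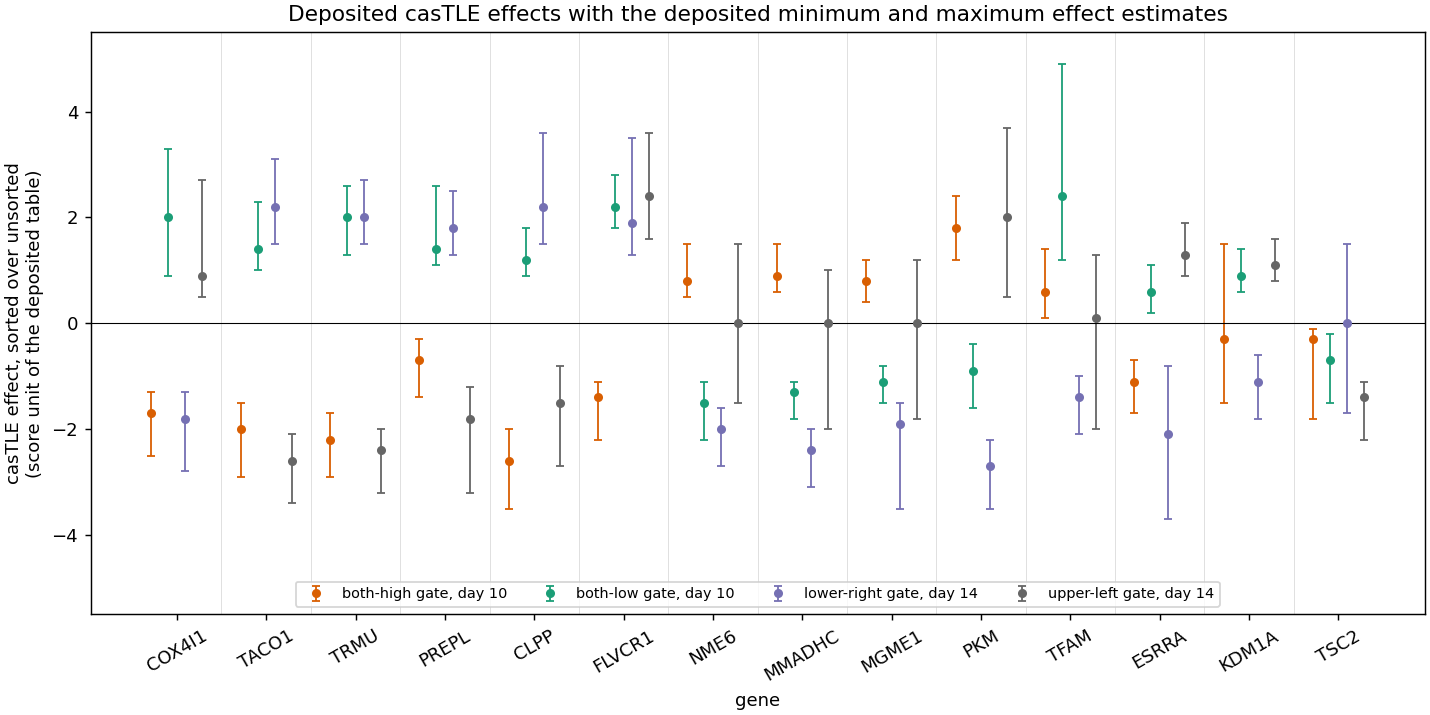
Points give the deposited casTLE effect, sorted over unsorted cells in casTLE's own unit, of 14 named genes (x axis) in 4 gates (colours), and bars run from the deposited minimum to the deposited maximum effect estimate. TRMU lay at -2.2, 2.0, 2.0 and -2.4 in the both-high, both-low, lower-right and upper-left gates, and NME6 at 0.8, -1.5, -2.0 and 0.0.

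Calls were also shared across days, where the unsorted libraries differed. The both-low gate of day 10 and the lower-right gate of day 14 shared 130 enriched genes against 5.92 expected (exact test, adjusted p = 5.1e-145) and 36 depleted genes against 1.55 expected (exact test, adjusted p = 3.6e-41), and their log2 fold changes correlated across genes at r = 0.37, against 0.12 among olfactory receptor genes. By casTLE calls the enriched overlap held 40 genes against 0.562 expected. The upper-left gate shared enriched genes with the both-low gate as well, 25 against 6.94 expected (exact test, adjusted p = 7.3e-08), among them NDUFAF3, PNPT1 and RPUSD4. casTLE calls left 4 genes in this overlap, against 0.245 expected. The casTLE effect of RPUSD4 was 2.7 lower in the upper-left than in the lower-right gate. Depleted genes of the upper-left gate held 8 that were enriched in the both-low gate, against 0.261 expected (exact test, adjusted p = 2.2e-10). The upper-left and both-high gates shared 9 enriched genes against 1.64 expected (exact test, adjusted p = 5.9e-05). They shared 6 depleted genes against 0.0557 expected (exact test, adjusted p = 4.0e-11). COX4I1 and COX5A were among only 6 genes enriched in the both-low and depleted in the lower-right gate, with KDM1A, POLG2, RBM39 and MRP63, against 6.80 expected. PREPL was enriched in the both-low gate at a deposited log2 fold change of 0.73, and stood at -0.45 in the both-high gate (FDR 0.487). TFAM was called in the lower-right gate alone among the 4 deposited MAGeCK tables, with 0.24, 0.15 and -0.09 in the both-high, both-low and upper-left gates. Its casTLE effect in the both-low gate, not called, was 2.4 (1.2 to 4.9). LRPPRC, a stabiliser of mitochondrial mRNAs, was called in none of the 4 gates by either tool, with deposited log2 fold changes between -0.17 and 0.13. Its casTLE effect in the both-low gate was 2.5 (1.3 to 4.9). Of the 30 lists, complex III, coenzyme Q synthesis, and hypoxia and integrated stress response passed the exact test in no gate, with 1, 1 and 3 as their highest counts of members called in one direction of one gate. By medians against random lists, a gene permutation test, complex III passed in the both-low gate (0.104, adjusted p = 0.0255) and the upper-left gate (-0.121, adjusted p = 0.0165). Coenzyme Q synthesis passed the gene permutation test in the both-low gate (0.101, adjusted p = 0.0452).

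Olfactory receptor genes served as the background of the calls. None of 388 was called in either day 10 gate by the deposited MAGeCK tables, which allows a share of up to 0.946% (exact binomial interval). The lower-right gate had 1 enriched and 5 depleted, 1.29% (0.42% to 2.98%) for the latter, and the upper-left gate had 4 enriched, 1.03% (0.282% to 2.62%), and 0 depleted. Over all genes, MAGeCK called 2.55% depleted in the lower-right gate and 2.60% enriched in the upper-left gate. The olfactory intervals include these 2 shares, so how much of these calls is background is unclear. At day 10 the shares over all genes were 0.308% enriched and 0.279% depleted in the both-high gate, and 1.30% and 0.298% in the both-low gate. The olfactory intervals, up to 0.946%, include all of these but the both-low enriched share, so the background of the other day 10 calls is unclear too. The deposited casTLE tables called 1 olfactory receptor gene enriched and 2 depleted in the both-low gate and none in the other gates. Per the labels each group had 2 replicates, and nothing stated that they came from separate cultures. The deposited p-values rest on the agreement among the sgRNAs of a gene in these samples, so they do not measure the spread between separate cultures, and agreement between replicates can be technical.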

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

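The tests of near-identical copies and of the shared unsorted libraries below were chosen only after their results were seen. When the test of growth members against other enriched genes was chosen was not recorded. The other tests of this part were written before.

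The named genes of the report were compared between the 2 gates of each day, as the deposited casTLE effect in one gate minus that in the other, with errors from the deposited intervals. At day 10, 77 of 109 named genes with casTLE values differed (normal approximation, adjusted over all genes). Over all genes, 325 of 20364 differed. The named genes were mostly chosen by their calls in these same gates, so a higher share among them follows from the choice. Both-high minus both-low effects below 0, from the authors' deposited casTLE tables, were -4.8 in TOMM70A, -4.7 in PARS2, -4.3 in GTPBP3, -4.2 in TRMU and -4.1 in YBEY. Smaller gaps between these gates were -4.0 in COX8A, MTO1 and NDUFAF3, -3.9 in TFB2M, -3.8 in CLPP and MCAT, -3.7 in COX4I1 and EARS2 and -3.6 in CARS2, FLVCR1, MRPL1 and PDHB. Further day 10 differences below 0 were -3.5 in GTPBP10 and MTRF1L, -3.4 in C12orf65, COA7, MRPS27, TACO1 and WARS2, -3.3 in COA3, COX15, COX7C, LIAS and MRPS34, -3.2 in MECR, METTL17 and N6AMT1 and -3.1 in BOLA3, NSUN4 and TOMM20. The next values on this side were -3.0 in COX18 and NDUFAF5, -2.9 in ATP5I and SARS2, -2.8 in CS and MRPS31, -2.7 in COX5A and NOA1 and -2.6 in AMD1, COX5B, MIPEP and NDUFA1. The remaining ones below 0 were -2.5 in NFU1, NUBPL, SCAF4 and SEPSECS, -2.3 in ATPAF2, -2.2 in ISCA2 and NDUFC2, -2.1 in AIFM1 and PREPL and -2.0 in NDUFA8 and PUS1. At the low end stood -1.9 in TRAP1, -1.8 in RMND1 and TMEM261 and -1.6 in PPARGC1B. On the other side, both-high minus both-low effects above 0 were 4.1 in LAMTOR2, 3.4 in TPI1, 3.2 in NUDT2, 2.9 in TYMS and 2.7 in PKM. Further values above 0 were 2.6 in PHF5A, 2.3 in NME6 and PSMD2, 2.2 in MMADHC, 1.9 in GPI and MGME1 and 1.8 in RPE. The smallest above 0 were 1.7 in CHD8, 1.3 in SLC25A33 and 1.2 in SLC25A5.

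At day 14, 44 of 143 named genes with casTLE values differed between the lower-right and the upper-left gate by the same test. Over all genes 200 of 20365 differed, and here too the named genes were mostly chosen by their calls in these gates. Lower-right minus upper-left effects below 0, from the authors' deposited casTLE tables, were -6.2 in ATP1B3, -4.7 in PKM, -3.9 in KLF1, -3.7 in GATA1 and -3.4 in ESRRA. Mid-sized day 14 differences below 0 were -3.0 in MYB, -2.9 in RCOR1, -2.7 in COX4I1, -2.5 in GPI and MED12 and -2.4 in MLST8 and PDPK1. Further day 14 differences below 0 were -2.2 in KDM1A and SP1, -2.1 in LAMTOR2, -2.0 in TADA2B and -1.7 in AZIN1. The smallest day 14 values below 0 were -1.5 in TAF6L. Lower-right minus upper-left effects above 0 were 5.1 in ANGEL2, 4.9 in MTO1, 4.8 in COX8A, PDE12 and TACO1, 4.4 in TRMU and 4.2 in CMC1. Mid-sized day 14 differences above 0 were 4.1 in EARS2, 3.8 in BOLA3 and TUFM, 3.7 in CLPP and NDUFB7, 3.6 in PREPL and YBEY and 3.4 in MRPS34. Further day 14 differences above 0 were 3.2 in COA3, SCO2 and TOMM20, 3.1 in PUSL1, 2.7 in RPUSD4 and 2.6 in PUS1. The smallest day 14 values above 0 were 2.5 in RMND1, 2.2 in NDUFC2 and 2.1 in COX5B.

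Genes needed for growth, 21 of 78 of the cytosolic ribosome and 7 of 42 of the spliceosome, were frequent among the enriched calls of the upper-left gate, whereas the proteasome had 2 of 36 (Fisher's exact test, adjusted p = 0.524). Noise in the shared day 14 unsorted libraries stays open. In the upper-left gate, the 30 called members of these 3 lists lay above the other members. Their medians differed by 0.37 in log2 fold change (bootstrap interval 0.16 to 0.47). This gap follows from choosing the members by their calls in that gate, so it is no evidence by itself. In the lower-right gate, on the same unsorted libraries, the gap was 0.214 (0.037 to 0.33). However, 5 of the 30 were enriched and 4 depleted there. The whole cytosolic ribosome list had medians of 0.125 in the upper-left and -0.135 in the lower-right gate. Noise from sgRNAs lost with growth stays open too: of the called members with casTLE values, 16 of 29 (55.2%, exact interval 35.7% to 73.6%) carried the sign of the call in both casTLE inputs, against 136 of 137 mitochondrial members in the both-low gate (Fisher's exact test, p = 1.2e-10). Other enriched genes of the upper-left gate did so in 337 of 499 (67.5%), and Fisher's exact test between these and the growth members gave p = 0.222, so weak growth sgRNAs and a gate with weaker calls in general cannot be told apart. A biological change in these cells was not tested.

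Immunoglobulin lambda segments, which lie on chromosome 22 near BCR, were enriched in the upper-left gate for 13 of 49, and for 2 by casTLE, while in the lower-right gate 4 were enriched and 6 depleted. Of the other receptor segments, 2 of 285 were enriched (Fisher's exact test, p = 2.7e-10). This argues against near-identical copies as the cause only if these segments are as repetitive as the lambda segments. That was assumed and could not be checked without values per sgRNA. Copy number around BCR stays open as a candidate explanation, since Cas9 breaks in amplified DNA may slow growth: genes of chromosome 22 up to BCR, without the lambda segments and 3 genes seen earlier, were enriched for 8 of 86 against 6 of 340 beyond BCR (Fisher's exact test, p = 0.00213). Of 6 genes from ABL1 to NUP214 on chromosome 9, the other side of the fusion, 2 were enriched. The design names no biological explanation, and none was tested.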

How the results depend on the processing

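The 2 alternatives of this part that ask for the same direction in both casTLE inputs, of calls and of differences between gates, were chosen after seeing the data; the others were set before. Counts are given in the order both-high, both-low, lower-right, upper-left, enriched before depleted. FDR recomputed from the deposited p, at least 8 sgRNAs and at least 4 good sgRNAs kept all 8 counts of called genes within 1.5 times. Casting calls by casTLE moved the count of enriched genes to 23 in the both-high gate, of depleted genes to 115 in the both-low gate, of both to 55 and 73 in the lower-right gate and of enriched genes to 24 in the upper-left gate. Calls of both tools numbered 12, 29, 164, 35, 49, 63, 21 and 9. FDR under 0.01 gave 14, 31, 159, 28, 186, 209, 185 and 8. FDR under 0.1 moved 6 counts, to 127 (both-high enriched), 127 (both-low depleted), 803 and 822 (lower-right) and 851 and 40 (upper-left). FDR under 0.25 gave 705, 148, 665, 253, 1688, 1880, 2958 and 58. A log2 fold change of at least 0.5 moved 6 counts, to 23 (both-high enriched), 33 (both-low depleted), 171 and 216 (lower-right) and 95 and 13 (upper-left). The same direction in both casTLE inputs left 353 of the upper-left enriched genes. These counts fell or rose with the number of genes each threshold admits; why the tools differed was not tested.

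With listed genes as background, whose members share many of the calls, passing lists numbered 2 of 12, 7 of 18, 5 of 21 and 1 of 11 in the 4 gates. By casTLE calls they numbered 13 in the lower-right and 5 in the upper-left gate, where FDR under 0.1 and 0.25 gave 18 and 21. Of 62 passing list results, casTLE kept 39 past the threshold with the same direction, listed genes as background 15, FDR under 0.1 or 0.25 each 60, at least 8 sgRNAs all 62, and random lists 49. The enriched cytosolic ribosome list of the lower-right gate was reversed by its median, -0.135, against random lists; its members were called in both directions.

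Overlaps moved as follows; the cause was not tested. Both-high depleted with both-low enriched gave 98 genes at FDR under 0.25, and both-high enriched with both-low depleted 5 by casTLE (0.129 expected) and 42 at 0.25. Lower-right enriched with upper-left depleted gave 16 at 0.1 and 22 at 0.25. Lower-right enriched with upper-left enriched gave 3 by casTLE (0.0645 expected), 229 at 0.1 and 807 at 0.25. Lower-right depleted with upper-left enriched gave 0 by casTLE (0.0856 expected), 101 at 0.1 and 439 at 0.25. Enriched genes of the both-low and lower-right gates shared 40 by casTLE (0.562 expected) and 297 at 0.25, and depleted ones 61 at 0.1 and 126 at 0.25. Correlations of casTLE effects in place of log2 fold changes turned sign for both-high with both-low (0.0574) and for both-low with upper-left (-0.00705). Differences by non-overlapping intervals numbered 724 at day 10 and 541 at day 14.

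Of 289 values of named genes, the casTLE effect kept the direction, and for called genes also the call, of 171 and reversed 7. Leaving out an input compared only the sign of the other input's effect, without a call. By this sign, leaving out input 1 kept 266 and reversed 17, and leaving out input 2 kept 276 and reversed 9. By casTLE effect, HSPE1 (-1.5), RPL7 (-1.3), RPS9 (-0.9) and RPS23 (-1.1) reversed in the lower-right gate, and IGLV2-14 (-1.1), SNRPD1 (-1.1) and MPV17L2 (2.3) in the upper-left gate; the cause was not tested. Effects with 1 input left out ranged from -1.2 to 2.2 for SNRPD3 in the both-high gate. In the lower-right gate they ranged from -0.1 to 1.3 for AARS2, -1.6 to 0.0 for HSPE1, -1.6 to -1.0 for RPL7, -0.3 to 1.4 for RPL35A, -0.8 to 1.3 for RPS9, -1.2 to 2.5 for RPS23, -1.1 to 2.1 for RPL12, -2.1 to 2.9 for PRPF19 and -0.9 to 0.4 for U2AF1. In the upper-left gate they ranged from -1.1 to 1.2 for IGLV2-14, -0.8 to 1.2 for HSPE1, -1.1 to 2.5 for AL353608.1, -0.7 to 2.4 for AL590867.1, -1.8 to 2.2 for TIMM23, -1.2 to 1.4 for HSPA9, -0.6 to 1.9 for DNM1L, -0.5 to 2.4 for PTPMT1, -1.3 to 1.9 for CRLS1, -1.1 to 0.8 for SNRPD1, -3.0 to 1.0 for SNRPF, -0.4 to 2.3 for ABL1, -2.1 to 0.4 for RMI1, -1.0 to 1.4 for METTL17 and -1.6 to 2.3 for MPV17L2.

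No paired analysis was possible because a fit of sorted with unsorted libraries needs values per library, which the tables do not carry. The depth that limits each value is unknown. The gates of a day could still be compared within the numbered casTLE inputs. Inputs of the same number correlated between the gates of a day among olfactory receptor genes at r = 0.34 and 0.27 at day 10 and 0.48 and 0.34 at day 14, and inputs of different numbers at -0.18 to 0.039. Within both inputs, 302 of the 325 differences of day 10 and 181 of the 200 of day 14 kept their direction.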

Other observations

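The test of the axes of the day 14 gates was chosen only after its result was seen; the tests of pathway members were written before the values of the unseen members were read.

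Enzymes of glycolysis and the pentose phosphate pathway, which held no list of their own, were depleted in the lower-right gate for 10 of 33 genes, of which 7 had been seen before the pathway was drawn up. Log2 fold changes in the authors' deposited MAGeCK table were -0.92 for ENO1, -0.79 for TKT, -0.60 for PGD, -0.53 for PGAM1 and -0.52 for PGK1, beside GPI, PKM, HK2, PFKP and PGP of the report. TPI1 was called enriched there at -0.18, with casTLE bounds from -3.0 to 3.0. At day 10, GPI, HK2, PFKP and TKT were depleted in the both-low gate, and HK2, TPI1, PKM, PGP and RPE were enriched in the both-high gate. The hypothesis of a depletion of the whole pathway was tested on the 24 members whose values had not been seen: 3, PGK1, PGAM1 and PGD, were depleted (Fisher's exact test, p = 0.0216). Loss of glycolysis may thus move cells out of the lower-right gate, a hypothesis found and tested on the same tables. The proteasome, spliceosome and cytosolic ribosome also passed among the depleted lists of this gate. A test against all other genes therefore cannot separate glycolysis from a wider depletion that includes growth machinery.

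Selenocysteine synthesis had SEPHS2 and SEPSECS enriched in the both-low gate, at log2 fold changes of 0.84 and 0.72 in the authors' deposited MAGeCK table, 2 of 9 members, both seen before the pathway was drawn up. In the lower-right gate the deposited values were 0.79 for SEPHS2, 0.51 for SEPSECS, 0.59 for the selenocysteine elongation factor EEFSEC and 0.44 for TRNAU1AP, all enriched, while SARS, the serine tRNA synthetase, was depleted at -0.45. An enrichment of the whole pathway may underlie this, but in the both-low gate 0 of 7 unseen members were called (Fisher's exact test, p = 1), too few to decide. Their deposited casTLE effects there were 1.5 (0.9 to 3.0) for TRNAU1AP, 1.0 (0.5 to 1.7) for EEFSEC, 1.0 (0.2 to 2.1) for PSTK and 0.9 (0.6 to 1.7) for TXNRD1. SARS went the other way at -2.3 (-3.9 to -0.4), and the bounds of SECISBP2 and SCLY spanned 0. In the both-high gate, SEPSECS and TRNAU1AP were called depleted.

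Polyamine synthesis had AMD1 and SMS, which make decarboxylated S-adenosylmethionine and spermine, enriched in the both-low gate at deposited log2 fold changes of 0.95 and 0.65, 2 of 13 members, both seen before the pathway was drawn up. In the lower-right gate they were enriched at 0.65 and 0.88 in the deposited table, while ODC1, the first enzyme of the pathway, and AZIN1, which protects it, were depleted at -0.53 and -0.90. In the both-low gate itself members went both ways: deposited casTLE effects were -1.1 (-1.9 to -0.3) for ODC1, -0.7 (-1.6 to -0.2) for SRM and -0.5 (-2.8 to -0.3) for AZIN1, but 1.9 (1.4 to 3.9) for DHPS. An enrichment of the whole pathway thus had no support: 0 of 10 unseen members were called (Fisher's exact test, p = 1), too few to exclude it.

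Which stain lay on which axis at day 14 was not stated. A candidate explanation of the opposite calls of both gates is a lower-right gate of cells with less COX1 relative to COX4. Among 145 members of the lists of the mitochondrial ribosome, its assembly, mitochondrial RNA processing and mitochondrial transcription, 123 (84.8%) had a higher casTLE effect in the lower-right than in the upper-left gate (exact binomial test, p = 3.2e-18). COX4I1 went the other way, at -1.8 in the lower-right and 0.9 in the upper-left gate of the authors' deposited casTLE tables. The calls that led to this hypothesis came from the same tables, and the labels leave it open.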
